A study of Mus musculus with 36 samples.

How the data were processed

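The series covers 36 libraries from 3 mouse T-cell acute lymphoblastic leukaemia (T-ALL) lines that had been induced by Notch, in 12 groups of 3. Lines 969 and 970 carry floxed Cdc73 and a CreERT2 recombinase in the Rosa26 locus, and line 708 carries the recombinase with wild-type Cdc73, per the labels. Cells received 4-hydroxytamoxifen (OHT, 6 nM) or ethanol vehicle (EtOH) for 30 h, and bromouridine (2 mM) over the last 0.5 h, per the labels' protocols. Bru-seq sequences the RNA that took up bromouridine and so measures transcription during the labelling time. In BruUV-seq the cells are irradiated before labelling, here with 200 J per square metre of UV-C, which blocks elongation and concentrates the signal at gene starts and enhancers. Groups and replicate numbers came from the sample titles, and the design text calls the 3 libraries of a group biological replicates.

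The authors deposited a count table of 18 Bru-seq libraries with 52114 genes on mouse build mm10 (GRCm38), as raw strand-specific read counts over each gene's whole span with introns included, as read from the spans in the table and the strand-specific library protocol in the labels. The 18 deposited per-library count files held the same counts as this table. A table of the authors' own comparisons gave, per the file headers, a log2 fold change and an adjusted p-value for each gene in each line. The deposited BruUV-seq peak lists were called per library and per strand, per the file headers and names, and give the authors' score, a fold enrichment (a ratio over local background), and the −log10 of a p-value and of a q-value for each summit. The lowest −log10 p in the lists corresponds to a p-value limit of 0.01 set by the authors. Several summits may share one interval, so the lists of 80747 to 122806 summits were reduced to 45514 to 72022 distinct intervals, called peaks here. A peak's score is the authors' own and was used only to rank peaks. Per the submitters' processing notes, CASAVA 1.8.2, Bowtie2 2.3.3, STAR 2.5.3a, bedtools 2.28.0, DESeq2 1.18.1, MACS2 2.2.7.1, DiffBind 3.6 and deepTools 3.5.1 were used. Which of them aligned, counted or called peaks is not given in the sources used here. Peak names inside the lists of 969 carry the number 172 in place of 969, so these lists were tied to line 969 by their sample record alone. The depth of the BruUV-seq libraries is unknown here, and a peak number also moves with depth.

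Library totals in the Bru-seq table ran from 42.2 M to 59.8 M counts (median 47.2 M), and the 10 highest genes took 2.39 to 3.21% of them. Counts differed between replicates by more than sampling noise in every pair (chi-square per degree of freedom 6.53 to 80.6), so no library was counted as a copy of another. The lowest correlation between replicates, on log2 CPM, was 0.985, in the OHT group of 969, where replicate 2 stood apart. Pairs with that library had a chi-square per degree of freedom of at least 79.9, and all other pairs at most 28.0. No gene of a spike-in or of the mitochondrial chromosome was among the counts used here (0 genes), so scaling to the spike-in that the protocol mentions was not run. All changes are therefore relative to the libraries' own counts, scaled by TMM in the main fit, and a shift of all transcription together would not be seen.

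Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group, TMM scaling, glmQLFit with robust estimation, glmQLFTest). One fit held all 18 libraries with a mean per group, 12 residual degrees of freedom and a common dispersion of 0.0109. The filter left 17734 genes, which held at least 99.96% of each library's counts. Contrasts were OHT against EtOH in 969, 970 and 708, the mean effect of 969 and 970 minus that of 708, and the effect of 969 minus that of 970. Adjusted p-values are Benjamini-Hochberg values over all genes of a contrast with a threshold of 0.05. Levels are given as CPM with the SD of 3 libraries. No libraries are shared between lines. There are 51 duplicated symbols in the table, and genes of one symbol were kept apart by their identifiers. Of the tested genes, 3418 overlap another tested gene on the same strand and may share its counts.

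Gene lists were tested with camera (limma 3.58.1) on voom values, with the correlation between genes preset at 0.01 and Benjamini-Hochberg adjustment over the lists of a contrast. Of 30 lists, 27 had at least the 5 tested members set as the minimum. Alternatives were camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way without comparing them with other genes. Long genes (at least 100 kb) were set against short genes (under 10 kb) through the log2 ratio of their summed counts in each library. Peaks were compared in number, covered length and share within 1000 bp of a gene start, with gene starts taken from the spans and strands of the count table. Regions were merged over the 18 lists on the same strand with 1 bp of overlap, which gave 132771 regions, of which 98445 occurred in at least 2 libraries. A region was called gained in a line when 3 of 3 OHT lists and 0 of 3 EtOH lists held it, and lost in the reverse case. Differences of per-library values were tested with exact two-sided permutation tests within lines. For a difference between lines, such a test asks whether OHT moved the value in any of them, not whether the lines moved alike. The 20 arrangements of one line allow no p below 0.10, the 400 of 969 and 970 together none below 0.005, and the 8000 of the 3 lines none below 0.00025. Intervals of shares are 95% Wilson intervals and cover counting error only.

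Groups, tests, lists, named-gene rule and most alternatives were set before the data were examined. Genes named in the text are the Paf1 complex subunits. To these the rule adds the 10 genes up and 10 down with the largest smaller change in 969 and 970, among genes past the threshold in 969, in 970 and against 708, with at least 5 CPM and no overlap of OHT and EtOH libraries. For 969 and 970 alone and 708 it adds 5 genes each way, for 969 minus 970 it adds 3 each way, for each list up to 4 members with the smallest adjusted p (any member of a list of at most 10), and up to 5 regions of each kind with the highest score. Predicted genes, microRNA, snoRNA and pseudogene symbols were passed over, and 3 genes that the rule picks are not reported here. Alternatives were DESeq2 1.42.0, DESeq2-style size factors (RLE), library totals without TMM, no filter on low counts, at least 1 CPM in 6 libraries, a 2-fold minimum, each line fitted alone, the replicate number as a block, and leaving out each library in turn. For peaks they were a −log10 q of at least 5, a 500 bp window, the same number of top peaks in every list (45514), merging within 200 bp, another overlap rule and another presence rule. Counting summits, a replicate block for 3 peak results and peaks on the gene's strand only were chosen after seeing the data.

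Groups share replicate numbers, so it was checked whether libraries of one number deviate together from their group means. In 970 the correlations of the pairs were 0.213, 0.219 and 0.210, and in 708 they were 0.339, 0.253 and 0.338, all above the 0.1 set for pairing. In 969 they were 0.151, 0.0848 and 0.131, so 1 lay under that limit, while pairs of unlike number in 969 reached at most 0.00452.

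The edgeR fit, camera and the peak functions were tested on simulated data with known answers, while fry, the length ratio and the counts of regions were not. With 200 genes changed among 17450, the contrast of 969 and 970 minus 708 recovered 33.8% of 68 genes changed 1.5-fold, 68.2% of 66 changed 2-fold and 81.8% of 66 changed 4-fold, with 14 unchanged genes called. For 969 alone the shares were 47.1%, 75.8% and 93.9% with 11 unchanged genes called, and for 970 alone 44.1%, 74.2% and 89.4% with 7. Of 20 random gene lists, 1 was called. Genes were simulated independently and few of them changed, so these rates do not cover correlated genes or changes as broad as those found here. The peak functions gave 0 wrong answers over 400 simulated intervals each. Peak and length steps used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots were made with Matplotlib 3.10.9. The deposited RPKM table and the rounded copies of the authors' comparisons were not used here, since they hold the same libraries in another form.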

Results

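Nascent RNA was measured in 3 mouse T-ALL cell lines after OHT or vehicle. OHT activates the CreERT2 recombinase in all 3 lines, and only 969 and 970 carry a floxed Cdc73 gene, which encodes a subunit of the Paf1 complex that travels with RNA polymerase II. Line 708 has wild-type Cdc73 and shows what OHT and the active recombinase do without that target. There were 6 groups of 3 Bru-seq libraries, with 42.2 M to 59.8 M counts each, and 6 groups of 3 BruUV-seq libraries, given as peak lists. The series title names DNA damage and mitochondrial stress, and gene lists were set around these topics and around transcription, cell growth and T-cell identity.

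Counts over the whole span of Cdc73 (ENSMUSG00000026361.9, mm10 chr1:143598800-143702893, minus strand) did not fall after OHT. In 969 Cdc73 stood at 385.8 ± 16.8 CPM with vehicle and 411.3 ± 62.4 CPM with OHT (SD, n = 3 each). In 970 it stood at 350.9 ± 5.91 and 423 ± 15.6 CPM, and in 708 at 495.7 ± 86.9 and 532.7 ± 26.7 CPM. The log2 fold change was 0.09 (SE 0.11, adjusted p = 0.488, edgeR quasi-likelihood with Benjamini-Hochberg) in 969 and 0.10 (SE 0.11, adjusted p = 1) in 708. In 970 it was 0.27 (SE 0.11, adjusted p = 0.0482), at the threshold, and did not pass with DESeq2 (adjusted p = 0.0605), with RLE size factors (0.0506), without a filter on low counts (0.107) or without any 1 of the 6 libraries of 970 (0.0583 to 0.125), while it passed with library totals (0.0120), with 1 CPM in 6 libraries (0.0232), with the replicate block (0.0379) and with 970 fitted alone (1.2e-04). The authors' deposited table gives Cdc73 log2 fold changes of 0.08, 0.27 (adjusted p = 3.8e-08) and 0.11 in 969, 970 and 708. A sum over a gene of 104 kb checks nothing about a deleted part of it, so these values neither show nor exclude the recombination that the labels imply.

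The genes of the other Paf1 complex subunits moved both ways in 969 and 970 relative to 708. Paf1 rose by 0.68 on the log2 scale (SE 0.11, adjusted p = 1.1e-04), Ctr9 by 0.33 (SE 0.09, adjusted p = 0.00914) and Leo1 by 0.34 (SE 0.09, adjusted p = 0.00741), by edgeR with Benjamini-Hochberg adjustment. Wdr61 fell by 0.25 (SE 0.07, adjusted p = 0.00543), and the value of Rtf1 was 0.13 (SE 0.06, adjusted p = 0.140). Of the 6 subunit genes 3 rose, 1 fell and 2 did not pass, over all genes and adjusted over the list alone, and the list as a whole did not shift (camera adjusted p = 0.175). With library totals in place of TMM the value of Wdr61 was -0.15 and no longer passed, and that of Rtf1 was 0.22 and passed.

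The comparisons within each line ask what OHT changed there. In 969 the largest rises among genes of at least 5 CPM were in Fhdc1 (log2 fold change 3.70, SE 0.18), Naip1 (3.42, SE 0.19), Nek10 (3.42, SE 0.15), Map3k15 (3.20, SE 0.18) and Glis1, which went from 4.05 ± 0.523 to 46.0 ± 7.47 CPM (SD, n = 3). The minimum is a mean that includes the OHT libraries. With vehicle, Fhdc1 stood at 0.842, Naip1 at 1.06, Nek10 at 2.25 and Map3k15 at 1.88 CPM in 969. Naip1 has close paralogs, so its counts are less certain. In 970 they were in Ttc39a (4.13, SE 0.22), Nek10 (3.54, SE 0.14), Map3k15 (3.10, SE 0.17), Agbl2 (2.89, SE 0.14) and Glis1 (2.86, SE 0.13). The largest falls in 969 were in Slc7a11 (-1.97, SE 0.13), Nebl (-1.80, SE 0.17), Egfem1 (-1.61, SE 0.11), Ttc12 (-1.60, SE 0.14) and Spag7 (-1.59, SE 0.12), and in 970 they included Amot (-1.65, SE 0.19), Slc7a11 (-1.51, SE 0.12), Lmcd1 (-1.45, SE 0.10) and Setmar (-1.33, SE 0.14). Each of these genes had an adjusted p of at most 1.6e-06 in its line by edgeR, with no overlap between the 3 OHT and the 3 vehicle libraries.

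Of 17734 genes tested with edgeR and Benjamini-Hochberg adjustment, 9504 (53.6%) changed in 969, 5044 of them up and 4460 down. In 970, 7653 genes (43.2%) changed, 3931 up and 3722 down. With each line fitted alone the counts were 7202 in 969 and 9402 in 970, so the order of the lines turned. In 708 the count was 0 by edgeR, with 175 genes at an unadjusted p under 0.05, and DESeq2 called 1 gene. Among changes of at least 2-fold, 2279 genes rose and 414 fell in 969, and 1846 rose and 119 fell in 970. With library totals in place of TMM, the median log2 fold change of all genes in 969 moved from 0.03 to 0.15 and the share of rises among its calls from 53.1 to 65.4%. The authors' deposited table has 4011 genes higher and 3648 lower in 969, 3781 and 3606 of them also called here, and 4480 higher and 4363 lower in 970, 3598 and 3569 of them shared, with 0 called the opposite way.

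The gene nearest to the threshold in 708 was Lgi1, at a log2 fold change of 0.89 (adjusted p = 0.104, edgeR). The authors' deposited table calls Lgi1 (0.89, adjusted p = 1.1e-06) and Svep1 (0.50, adjusted p = 0.00373) in 708 and no other gene. Both were named after their values were seen. Svep1 had an adjusted p of 1 here by edgeR, and without OHT replicate 1 of 708 the edgeR count was 1.

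Lines 969 and 970 moved largely the same genes. Of the genes that rose, 3207 rose in both lines, where independent lists of these sizes would share 1118. Of those that fell, 2922 fell in both, against 936 for independent lists, and 18 and 21 genes were called in opposite directions. Across 10123 genes of at least 5 CPM, the log2 fold changes of 969 and 970 had Pearson's r 0.775 and Spearman's rho 0.785, and those of 969 and 708 had r -0.08 and rho -0.191. Genes are not independent replicates, and the lines share no libraries.

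**Figure D1:**
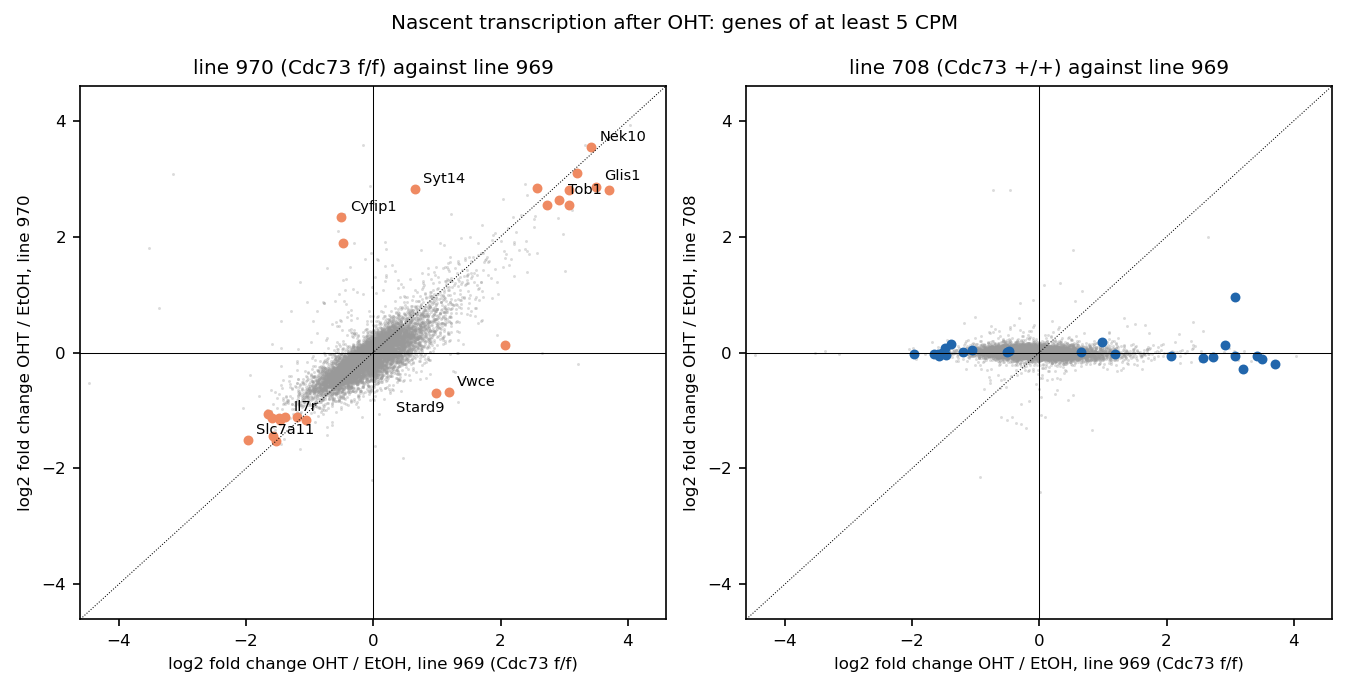
Log2 fold change of OHT over EtOH per gene, 970 against 969 on the left and 708 against 969 on the right, for 10123 genes of at least 5 CPM, with named genes coloured and a dotted line where both lines are equal. The values of 970 follow those of 969 (r 0.775), while those of 708 stay close to 0.

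The mean response of 969 and 970 minus that of 708 asks which changes go beyond what OHT does in the control line. Nek10, which encodes a NIMA-related kinase, rose 11.6-fold (log2 3.54, SE 0.18, adjusted p = 4.4e-10, edgeR). It went from 2.25 ± 0.392 to 24.3 ± 1.11 CPM in 969 and lies on mm10 chr14:14803415-15012059 (plus strand). Map3k15, a MAP kinase kinase kinase gene, rose 10.8-fold (log2 3.43, SE 0.24), the formin-family gene Fhdc1 10.9-fold (log2 3.45, SE 0.25), the zinc finger gene Glis1 9.82-fold (log2 3.30, SE 0.15) and Camk2a, a subunit of calmodulin-dependent kinase II, 7.99-fold (log2 3.00, SE 0.14). Agbl2 (2.95, SE 0.18), Stpg4 (2.79, SE 0.11), Pabpc1l (2.72, SE 0.16) and the antiproliferative gene Tob1 (2.65, SE 0.17) rose too. Egr1, an immediate early transcription factor, rose by 1.85 (SE 0.43, adjusted p = 0.00299), and its value in 708 was 0.96 (SE 0.34, adjusted p = 1).

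Slc7a11, the cystine-glutamate exchanger that feeds glutathione synthesis, had the largest fall of the genes named in this contrast. It fell by 1.72 on the log2 scale against 708 (SE 0.15, adjusted p = 2.1e-07, edgeR), from 841.1 ± 67 to 215.1 ± 22.6 CPM in 969 and from 1614 ± 59.5 to 566.6 ± 90.4 CPM in 970, while 708 stood at 78.2 ± 10.3 and 77.3 ± 12.2 CPM. Its span is mm10 chr3:49892526-50443614 on the minus strand. Il7r, the interleukin 7 receptor alpha chain, had a log2 fold change of -1.39 (SE 0.23, adjusted p = 1.6e-04), Lmcd1 at -1.45 (SE 0.12), Lgals9 (galectin 9) at -1.27 (SE 0.15) and F13a1 at -1.33 (SE 0.21). Spag7 (-1.33, SE 0.14), D5Ertd605e (-1.16, SE 0.19) and Lrguk (-1.15, SE 0.14) fell as well, and so did the iron exporter gene Slc40a1 (-1.38, SE 0.25), which was near the limit of detection in 970 (0.378 CPM with vehicle). In 708 the log2 fold changes of these genes lay between -0.28 and 0.14, Egr1 apart.

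Against 708, 6450 genes (36.4%) changed by edgeR with Benjamini-Hochberg adjustment, 3235 up and 3215 down. Of those changed at least 2-fold, 1591 rose and 174 fell, and 1143 of the 1591 had a vehicle mean under 1 CPM in 969 and 970. With library totals alone the median of all genes moved from 0.02 to 0.12 and the split from 3235 up and 3215 down to 4022 up and 2321 down. With 1 control line, genotype and line cannot be told apart in this contrast.

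Of the DNA repair lists, that of homologous recombination shifted down relative to 708 also with an estimated correlation, and the others did not. Of 39 genes of homologous recombination and the Fanconi anaemia pathway, which repair double-strand breaks and crosslinks, 24 fell, 1 rose and 14 did not pass (24 and 1 adjusted over the list alone). Fancl (-0.98, SE 0.07), Rad51b (-0.89, SE 0.07), Fancd2 (-0.85, SE 0.05) and Fanci (-0.76, SE 0.07) were among them. The median log2 fold change was -0.40 and the list shifted down (camera adjusted p = 5.5e-09, and adjusted p = 0.045 with an estimated correlation). Of 28 checkpoint and end-joining genes 12 fell, 3 rose and 13 did not pass (16 and 4 adjusted over the list alone), with the end-joining genes Nhej1 (-1.14, SE 0.10), Xrcc4 (-0.95, SE 0.10) and Xrcc5 (-0.65, SE 0.06) and the checkpoint kinase gene Atr (-0.89, SE 0.11) among those that fell. Their median was -0.26 (camera adjusted p = 0.00296, but adjusted p = 0.162 with an estimated correlation). Of 43 excision and mismatch repair genes 13 fell, 6 rose and 24 did not pass (14 and 7 adjusted over the list alone), among them Neil3 (-0.72) and Pms1 (-0.54) down, and the list did not pass (camera adjusted p = 0.0607), with 8 down and 8 up under library totals.

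Replication genes fell more often than they rose, and mitosis genes rose more often. Among all genes of at least 5 CPM, falls against 708 also outnumbered rises in each length group from 10 kb up. At 30 to 100 kb 34.2% fell and 12.8% rose, while under 10 kb 15.5% fell and 20.7% rose. More falls than rises therefore do not by themselves set a list apart, and camera is the test that compares it with other genes. Of 47 DNA replication genes 19 fell, 4 rose and 24 did not pass (19 and 5 adjusted over the list alone), among them the polymerase epsilon genes Pole2 (-0.75, SE 0.07) and Pole (-0.56, SE 0.06), the helicase gene Mcm6 (-0.45, SE 0.05) and Pold3 (-0.42, SE 0.06). Their median was -0.18 (camera adjusted p = 0.00194, but adjusted p = 0.159 with an estimated correlation). Of 36 mitosis genes 15 rose, 4 fell and 17 did not pass (the same counts adjusted over the list alone), with Cdc20 (1.05, SE 0.10), which activates the anaphase-promoting complex, the centromere histone gene Cenpa (0.89, SE 0.09), the separase gene Espl1 (0.77, SE 0.08) and Incenp (0.60, SE 0.07) up. Their median was 0.18 (camera adjusted p = 0.00383, but adjusted p = 0.159 with an estimated correlation). Of 61 replication-dependent histone genes, near-identical copies whose counts are uncertain, 8 rose, 1 fell and 52 did not pass (5 and 0 adjusted over the list alone), led by Hist2h2be (2.12, SE 0.23). The list did not pass (camera adjusted p = 0.0607), though it did with the replicate number as a block. In 969 alone 16 histone genes rose and 0 fell, and in 970 7 rose and 9 fell.

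Nuclear genes of the mitochondrial respiratory chain fell more often than they rose, as did all genes of at least 5 CPM in the length groups from 10 kb up. Of 76 genes of oxidative phosphorylation subunits 27 fell, 4 rose and 45 did not pass, over all genes and adjusted over the list alone. The complex II genes Sdha (-0.71, SE 0.08) and Sdhc (-0.50, SE 0.07), the ATP synthase gene Atp5c1 (-0.48, SE 0.06) and the complex I gene Ndufa7 (-0.56, SE 0.08) were among them, and the median of the list was -0.10 (camera adjusted p = 0.0116, but adjusted p = 0.240 with an estimated correlation), or -0.12 relative to all genes with library totals, where 20 fell and 7 rose. Of 47 assembly factor genes 18 fell, 2 rose and 27 did not pass (19 and 2 adjusted over the list alone), with Uqcc2 (-0.87, SE 0.13), Sdhaf3 (-0.66, SE 0.09), Cox15 (-0.55, SE 0.09) and Atpaf2 (-0.42, SE 0.07) down. This list shifted with a median of -0.22 (camera adjusted p = 0.00463, and adjusted p = 0.045 with an estimated correlation). The shift of the subunit list was lost when genes had to reach 1 CPM in 6 libraries.

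Other mitochondrial lists did not pass as a whole. Of 77 mitochondrial ribosome genes 27 fell, 14 rose and 36 did not pass (29 and 15 adjusted over the list alone), with Mrpl47 (-0.96, SE 0.10) and Mrpl48 (-0.69, SE 0.06) down and Mrps24 (0.93, SE 0.14) up (camera adjusted p = 0.0607), while under library totals 16 fell and 15 rose. Of 25 genes of mitochondrial genome maintenance and transcription 9 fell, 4 rose and 12 did not pass (11 and 5 adjusted over the list alone), among them the packaging factor gene Tfam (-0.47, SE 0.08), Mterf3 (-0.66, SE 0.06) and Tfb1m (-0.61, SE 0.09), with camera adjusted p = 0.0855, and under library totals more rose (7) than fell (6). Genes encoded by the mitochondrial genome were not analysed here.

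Of 31 targets of the integrated stress response factor ATF4, 16 fell, 3 rose and 12 did not pass (18 and 6 adjusted over the list alone). Besides Slc7a11, those that fell included the serine synthesis gene Psat1 (-0.52, SE 0.06), the mitochondrial folate enzyme gene Mthfd2 (-0.59, SE 0.07) and Eif4ebp1 (-0.62, SE 0.08), a repressor of translation. The median was -0.43 (camera adjusted p = 0.00296, but adjusted p = 0.159 with an estimated correlation). Of 28 p53 targets 12 rose, 3 fell and 13 did not pass (12 and 4 adjusted over the list alone), with the cell cycle inhibitor Cdkn1a (1.77, SE 0.18), the apoptosis effector Bax (1.02, SE 0.14) and Gtse1 (0.94, SE 0.11) up and the translesion polymerase Polk (-0.43, SE 0.09) down, and a median of 0.32 (camera adjusted p = 0.0264, but adjusted p = 0.159 with an estimated correlation). Gtse1 is a mitotic gene as well. Of 30 immediate early genes 18 rose, 0 fell and 12 did not pass (19 and 0 adjusted over the list alone), among them Ier5 (1.63, SE 0.17), Zfp36l1 (1.33, SE 0.11), Jun (1.00, SE 0.13) and Mcl1 (0.48, SE 0.08). Their median was 0.87 (camera adjusted p = 1.1e-05, but adjusted p = 0.159 with an estimated correlation).

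Of 36 T-cell identity genes 14 fell, 2 rose and 20 did not pass (15 and 2 adjusted over the list alone). Among them were Dntt, the terminal transferase (-0.99, SE 0.17), Themis (-0.68, SE 0.10), Ets1 (-0.58, SE 0.10) and Satb1 (-0.52, SE 0.09), and the median was -0.22 (camera adjusted p = 0.0104, but adjusted p = 0.240 with an estimated correlation). This shift, too, was lost when genes had to reach 1 CPM in 6 libraries. Among all genes of at least 5 CPM, 29.5% of those of 10 to 30 kb and 34.2% of those of 30 to 100 kb fell against 708. Of 48 ribosome biogenesis genes 19 rose, 4 fell and 25 did not pass (the same adjusted over the list alone), with Polr1b (0.40, SE 0.06), Noc2l (0.43, SE 0.07) and Nop2 (0.49, SE 0.10) up and Nop14 (-0.40, SE 0.08) down, and a median of 0.24 (camera adjusted p = 0.0104, but adjusted p = 0.302 with an estimated correlation). In all, 11 of 27 lists shifted against 708, 4 up and 7 down, and 2 of them held with an estimated correlation. The medians of all 11 kept their sign with RLE size factors and with library totals.

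Among the lists that did not pass, Notch targets went both ways, 4 up, 4 down and 11 not passed of 19, also adjusted over the list alone (camera adjusted p = 0.803). Myc (0.91, SE 0.10) and Ccnd1 (0.82, SE 0.17) rose, and Il7r and Cdk6 (-0.45, SE 0.06) fell. Of 30 elongation and pausing factor genes 10 rose, 4 fell and 16 did not pass (10 and 5 adjusted over the list alone; camera adjusted p = 0.306), with the P-TEFb inhibitor Hexim1 (1.12, SE 0.17), the H2B ubiquitin ligase subunit Rnf40 (0.63, SE 0.08) and Supt5 (0.48, SE 0.07) up and Mllt3 (-0.56, SE 0.07) down. Of 20 BCL2-family and death receptor genes 3 rose, 5 fell and 12 did not pass, also adjusted over the list alone, with Bmf (1.08, SE 0.15) up and Bcl2 (-0.67, SE 0.13) down. Their median was -0.02 and their mean 0.164, of opposite sign, and the median turned to 0.07 with library totals (camera adjusted p = 0.783).

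Of 18 TNF and NF-kB targets 6 rose, 1 fell and 11 did not pass, also adjusted over the list alone, with Nfkbia at 1.19 (SE 0.14; camera adjusted p = 0.112). Of 27 interferon response genes 5 rose, 3 fell and 19 did not pass, also adjusted over the list alone, with Oas3 (2.39, SE 0.36) up and Ifit2 (-0.81, SE 0.10) down (camera adjusted p = 0.495). Of 30 cholesterol synthesis genes 11 fell, 2 rose and 17 did not pass (12 and 3 adjusted over the list alone), with Acaca (-0.48, SE 0.07) and Stard4 (-0.72, SE 0.13) down (camera adjusted p = 0.0596). Of 30 glycolysis and hypoxia genes 8 rose, 3 fell and 19 did not pass, also adjusted over the list alone, with Pgam1 (0.84, SE 0.08) and Pkm (0.68, SE 0.07) up (camera adjusted p = 0.0607). Of 81 cytosolic ribosomal protein genes, which have many processed copies, 10 rose, 0 fell and 71 did not pass (9 and 0 adjusted over the list alone), with Rpl15 at 0.49 (SE 0.09; camera adjusted p = 0.0567). Of 28 heat shock and folding genes 5 rose, 5 fell and 18 did not pass, also adjusted over the list alone, with Dnajb1 (0.72, SE 0.10) up and Canx (-0.78, SE 0.10) and Pdia6 (-0.67, SE 0.08) down. Their median was 0.04, while camera put the list on the lower side (adjusted p = 0.932).

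Some markers of other blood cells rose, and the myeloid ones were near the limit of detection. Levels of the other marker lists are not given here. Of 5 tested myeloid markers 3 rose, 0 fell and 2 did not pass (4 and 0 adjusted over the list alone), namely Adgre1 (2.74, SE 0.48), one of 2 genes under the symbol Itgam (2.76, SE 0.49) and Cd68 (0.65, SE 0.19), at a median level of 0.364 CPM (camera adjusted p = 0.0567, and 0.0347 in 970, but adjusted p = 0.126 with an estimated correlation there), and the list passed against 708 when any 1 library other than OHT replicate 3 of 969 was left out. Of 4 B-cell markers Cd79a (1.79, SE 0.60), Blnk (1.15, SE 0.22) and Ighm (0.58, SE 0.22) rose, and of 4 erythroid and megakaryocyte markers Itga2b (1.75, SE 0.18) and Klf1 (1.70, SE 0.48) did. Of 5 stromal and endothelial markers Pecam1 (-0.73, SE 0.10) fell (camera adjusted p = 0.254). These rises went along with those of the lists above.

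**Figure D2:**
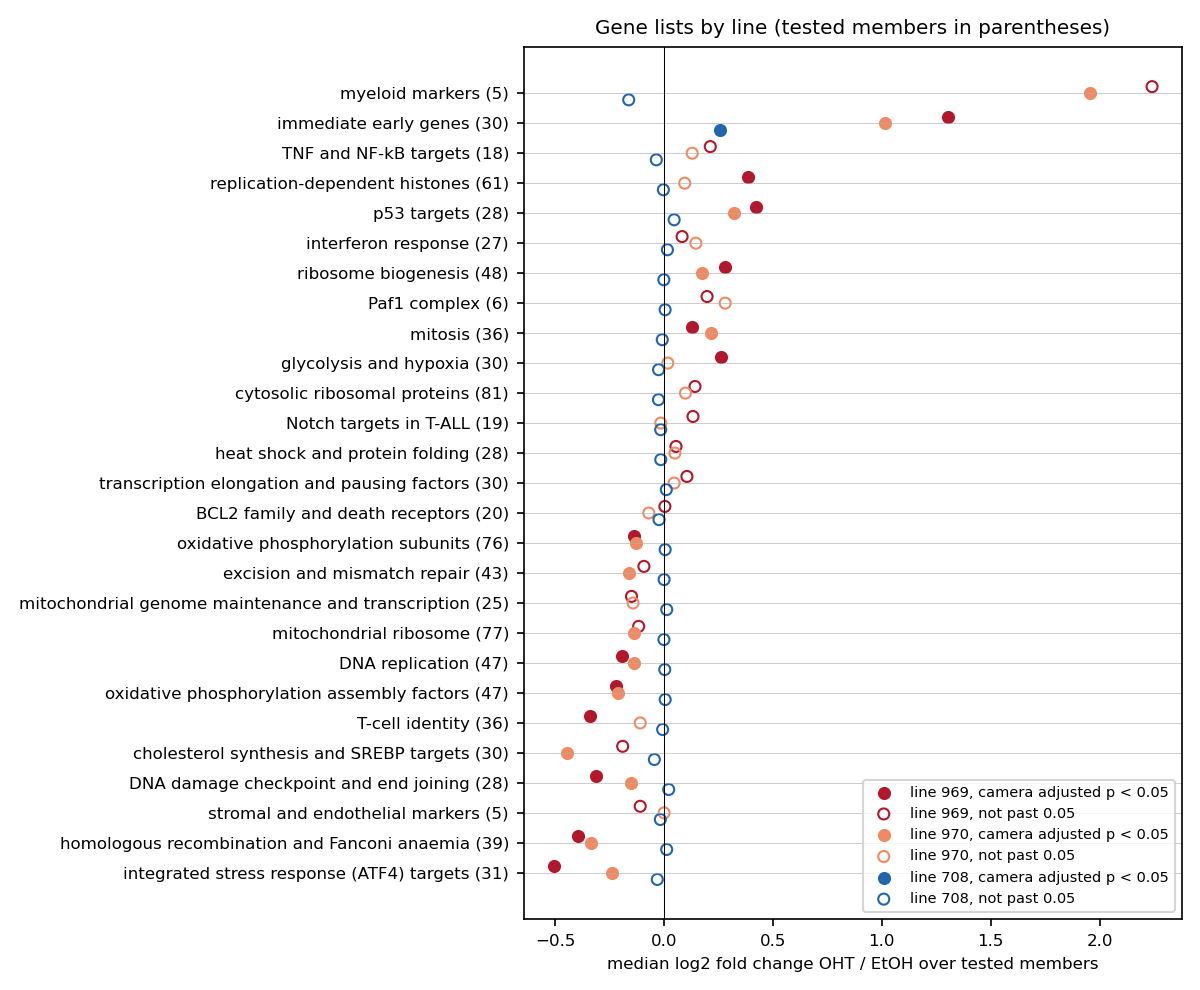
Median log2 fold change of OHT over EtOH for each gene list with at least 5 tested members in 969, 970 and 708, with filled points where the list shifted (camera adjusted p under 0.05). The list of homologous recombination and Fanconi anaemia genes lies at -0.40 in 969 and -0.33 in 970, that of immediate early genes at 1.30 and 1.01, and in 708 immediate early genes lie at 0.26, myeloid markers at -0.16 and the other lists nearer to 0. With library totals the median changed sign for excision and mismatch repair genes in 969, for Notch targets in 970 and for lists near 0 in 708, and with RLE size factors for BCL2-family genes in 969.

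Within the lines, 13 lists shifted in 969 and 14 in 970, 10 of them the same way in both, and 1 shifted in 708 (camera with Benjamini-Hochberg adjustment). With an estimated correlation 0 held in 969, 1 in 970 (oxidative phosphorylation assembly factors, adjusted p = 0.0325 with an estimated correlation) and 0 in 708. Homologous recombination and Fanconi genes fell in 27 of 39 cases in 969 (adjusted p = 5.9e-08, and adjusted p = 0.0696 with an estimated correlation) and in 30 of 39 in 970 (adjusted p = 1.0e-08, and adjusted p = 0.0515 with an estimated correlation). Immediate early genes rose in 23 of 30 and 22 of 30 cases (adjusted p = 6.1e-08 and 8.3e-07, and adjusted p = 0.124 and 0.126 with an estimated correlation). In 708 these same 30 genes had a median of 0.26 with 0 of them called by edgeR, Nr4a1 at 0.59 and Egr1 at 0.96, and the list shifted up (adjusted p = 2.0e-04, but adjusted p = 0.949 with an estimated correlation). That shift ended without vehicle replicate 1 or OHT replicate 3 of 708, and with the replicate numbers as a block 2 lists shifted in 708.

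The difference between the 2 floxed lines asks where their responses part. Syt14, a synaptotagmin gene, rose more in 970 (log2 fold change 2.83) than in 969 (0.66), with a difference of -2.17 (SE 0.15, adjusted p = 1.4e-07, edgeR). Vwce (difference 1.87, SE 0.17, adjusted p = 5.0e-06) and Stard9 (1.69, SE 0.20, adjusted p = 1.7e-04) rose in 969, from 3.33 to 7.59 and from 2.37 to 4.70 CPM, and fell in 970, from 36.1 to 22.4 and from 13.3 to 8.18 CPM. Cyfip1 (-2.84, SE 0.31, adjusted p = 6.0e-05) and Thsd4 (-2.38, SE 0.30, adjusted p = 2.6e-04) fell in 969 by log2 values of -0.50 and -0.48 and rose in 970, where they were nearly silent with vehicle, at 0.135 and 0.268 CPM against 51.2 and 16.1 CPM in 969. The phospholipase gene Pla2g16 (1.93, SE 0.31, adjusted p = 0.0024) rose in 969 from 0.427 CPM, against 17.3 CPM with vehicle in 970.

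In that contrast 320 genes differed by edgeR with Benjamini-Hochberg adjustment, 104 with the higher log2 fold change in 969 and 216 with the higher one in 970. DESeq2 gave 837 and the replicate block 774. Leaving out 1 library gave 153 (without vehicle replicate 1 or 3 of 970), 159 and 166 (without OHT replicate 3 or 2 of 970), 167, 169 and 194 (without vehicle replicate 1, 2 or 3 of 969) and 621 (without OHT replicate 1 of 969). The share with the higher value in 969 moved from 32.5 to 48.3% with library totals, to 50.6% without OHT replicate 1 of 969 (314 and 307 genes) and to 44.3% without its OHT replicate 3 (187 and 235), so it depends on single libraries.

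Glycolysis and hypoxia genes differed between the lines as a list, a test that was not among those planned. Their difference had a median of 0.30 (camera adjusted p = 8.7e-08, and adjusted p = 0.0235 with an estimated correlation), with 5 of 30 genes higher in 969, 0 lower and 25 not passed (11 and 0 adjusted over the list alone). These included the glucose transporter gene Slc2a1 (0.87, SE 0.16), Gpi1 (0.55, SE 0.08), Eno1 (0.79, SE 0.15) and Pfkl (0.94, SE 0.18). In 969 alone 15 of the 30 rose (median 0.26, adjusted p = 0.00407, but adjusted p = 0.124 with an estimated correlation) and in 970 4 rose and 6 fell (median 0.02, adjusted p = 0.952). T-cell identity genes lay lower in 969 (median -0.17, adjusted p = 1.0e-04, but adjusted p = 0.330 with an estimated correlation), with 0 up, 3 down and 33 not passed (0 and 5 adjusted over the list alone), namely Themis (-0.68, SE 0.11), Lef1 (-0.43, SE 0.08) and Lcp2 (-0.46, SE 0.09). Of 27 lists 8 differed between the lines and 1 held with an estimated correlation. The lists of this contrast were not tested with libraries left out, with another filter or scaling, or with the replicate block.

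Long genes lost part of their share of transcription in the floxed lines, a comparison made because Cdc73 belongs to an elongation complex. Genes of at least 100 kb took 32.6 ± 0.564% of the counts with vehicle and 29.6 ± 0.564% with OHT in 969 (SD, n = 3), and 33.2 ± 0.756% and 32.1 ± 0.526% in 970. Genes under 10 kb went from 8.08 to 9.88% in 969 and from 7.57 to 8.43% in 970. The log2 ratio of long over short genes changed by -0.43 in 969 and -0.21 in 970 (exact permutation p = 0.10 each, the smallest possible) and by 0.02 in 708 (exact permutation p = 0.40). Over 969 and 970 together it changed by -0.32 (exact permutation within lines, two-sided, p = 0.005, the smallest possible), and by -0.34 relative to 708 (p = 0.001). The difference between 969 and 970 was -0.23 (exact permutation p = 0.34). Arrangements that keep the OHT response of one line whole widen the spread of this test, so it does not decide whether the lines differ. The p-value relative to 708 likewise tests for no OHT effect in any line.

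By length, the median log2 fold change in 969 was 0.16 in 7159 genes under 10 kb, 0.03 in 4909 genes of 10 to 30 kb, -0.04 in 3963 genes of 30 to 100 kb and -0.17 in 1703 longer genes. In 970 the 4 medians were 0.07, -0.04, -0.02 and -0.04, so the medians of 970 showed little of the trend in its summed counts. Against 708, 8.02% of genes under 10 kb and 29.9% of genes of at least 100 kb fell by edgeR, and 18.1% and 13.7% rose. Among genes of at least 5 CPM, 15.5% and 41.0% fell and 20.7% and 9.39% rose. Slc7a11, of 551 kb, and Egfem1, of 608 kb, are among the long genes that fell, while Nek10 and Glis1, at 209 and 200.3 kb, rose.

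**Figure D3:**
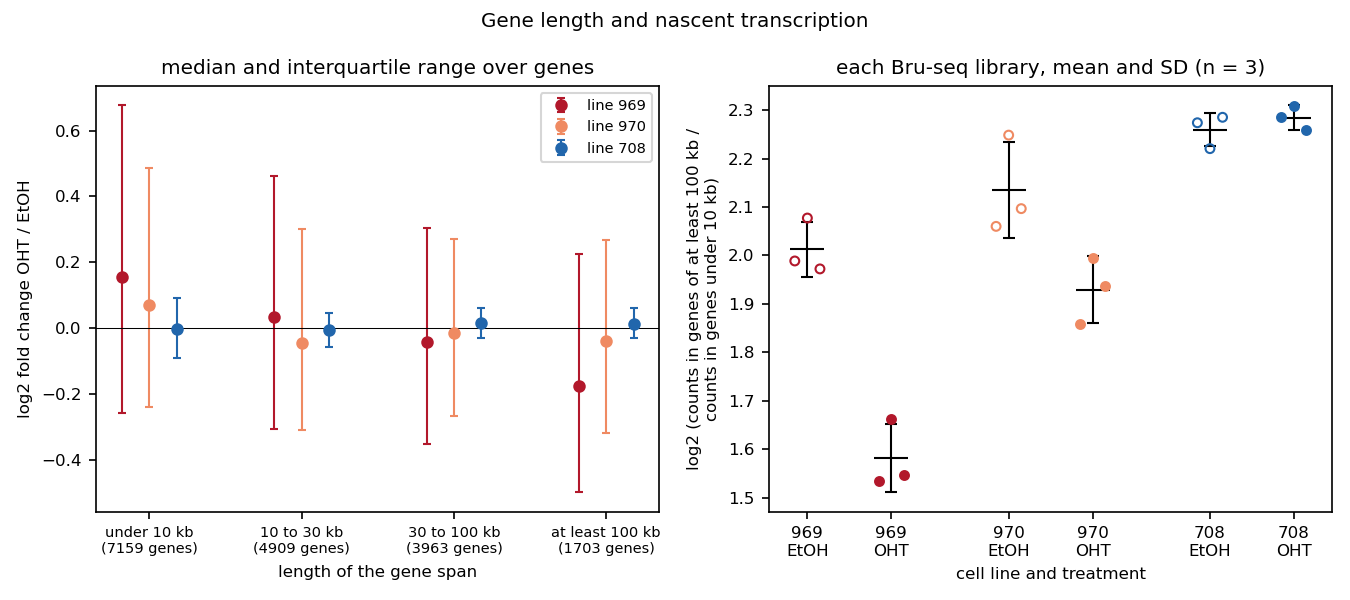
Left, median (with the interquartile range) of the log2 fold change of OHT over EtOH by gene length in each line; right, log2 ratio of counts in genes of at least 100 kb over genes under 10 kb per library, with mean and SD (n = 3). In 969 the ratio goes from 2.01 ± 0.06 to 1.58 ± 0.07, in 970 from 2.13 ± 0.10 to 1.93 ± 0.07, and in 708 it starts at 2.26 ± 0.03 and changes by 0.02.

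BruUV-seq concentrates the signal at active gene starts and enhancers, and the number of peaks was compared between OHT and vehicle. Inside genes and away from starts lay 55.8 to 74.7% of a library's peaks. The number therefore need not count active starts and enhancers alone. In 970 the mean number went from 60261 with vehicle to 50788 with OHT, a log2 difference of -0.25 (exact permutation p = 0.1, the smallest possible). In 969 it went from 53687 to 55033 (0.05, p = 0.8) and in 708 from 60877 to 62298 (0.05, p = 0.9, exact permutation). Over 969 and 970 the difference was -0.10 (exact permutation within lines, p = 0.365). The length covered by peaks in 970 went from 73.1 ± 1.25 to 62.4 ± 2.68 Mb (SD, n = 3, exact permutation p = 0.1), and in 969 it differed by -1.43 Mb (exact permutation p = 0.8). Over both lines it differed by -6.04 Mb (exact permutation p = 0.05), mostly through 970, and relative to 708 by -7.58 Mb (exact permutation p = 0.299).

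The share of peaks within 1000 bp of a gene start was 28.5 ± 6.87% with vehicle and 26.0 ± 3.17% with OHT in 969 (SD, n = 3; exact permutation p = 0.5). It was 22.9 ± 0.763% and 28.2 ± 2.5% in 970 (exact permutation p = 0.1) and 24.4 ± 7.41% and 23.6 ± 3.13% in 708 (exact permutation p = 0.9). Over 969 and 970 the difference was 1.32 percentage points (exact permutation p = 0.6), less than the spread between replicates. Signs in 969 and 708 turned under other settings, and peak numbers also move with a depth that is unknown here.

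**Figure D4:**
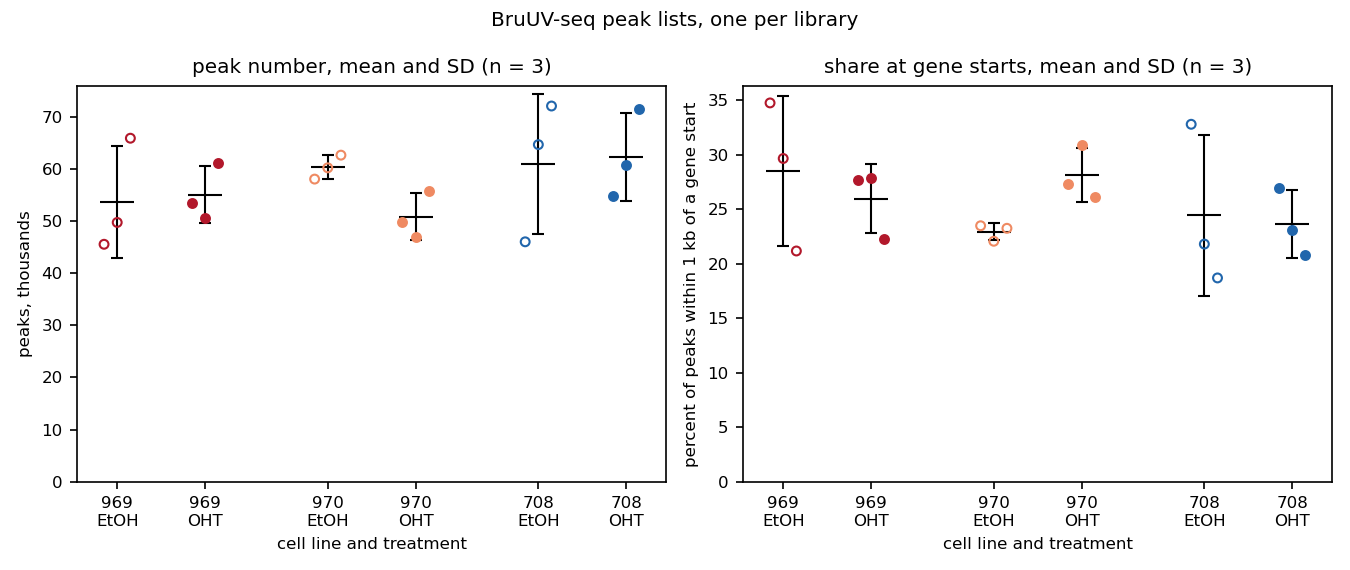
Number of BruUV-seq peaks (in units of 1000, left) and percent of peaks within 1000 bp of a gene start (right) in each library, with mean and SD (n = 3) and filled points for OHT. In 970 the OHT libraries lie below the vehicle libraries in number and above them in share, and in 969 and 708 the groups overlap.

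Peaks at the starts of genes changed in Bru-seq ask whether start activity moved with transcription in separate libraries. Among 3235 genes that rose against 708, the share with a peak at the start minus that of 11284 other genes went from -8.54 to -6.66 percentage points in 969 and 970 (difference 1.88, exact permutation within lines, p = 0.01). In 708 it moved by -0.50 (exact permutation p = 0.3), and the difference from 708 was 2.38 points (exact permutation p = 0.0015). The latter p-value tests for no OHT effect in any line, not for equal effects. The share itself went from 53.7 to 55.0% (exact permutation p = 0.12) and that of the other genes from 62.2 to 61.6%. Among 3215 genes that fell, the share minus that of other genes moved by -0.80 points in 969 and 970 (exact permutation p = 0.03) and by -0.59 in 708 (p = 0.3), and the difference from 708 was -0.22 (exact permutation p = 0.737). With a 500 bp window this value for the fallen genes was -0.54 (p = 0.345), and with replicate numbers as pairs neither change of 969 and 970 passed (exact sign-flip permutation, p = 0.0625 for each).

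Regions present in all OHT lists and no vehicle list, or the reverse, ask which sites appeared or were lost. In both floxed lines and not in 708, 56 regions were gained and 32 lost. The gained region with the highest authors' score (mean 704) lay over the start of the histone gene Hist1h1d on the opposite strand (mm10 chr13:23552334-23556078, minus strand). Others were within A630091E08Rik (chr7:98556456-98558694, minus), 36 bp from the start of Arl4d (chr11:101665577-101667748, plus), 367 bp from the start of Mef2d on the other strand (chr3:88141055-88142005, minus) and outside genes (chr6:47674225-47675085, plus). Lost regions included one 734 bp from the start of Fam169b (chr7:68274573-68275233, plus, mean score 749), one 4272 bp from the start of the stress response gene Ppp1r15a (chr7:45520643-45521996, minus), one outside genes (chr15:74903824-74904455, minus), one 2438 bp from the start of Mef2d (chr3:88138955-88139934, minus) and one within Mprip (chr11:59665533-59667005, plus).

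Of 400 arrangements of the labels within lines, 3 gave at least as many regions as the 56 gained and 10 as many as the 32 lost (the most in any other arrangement was 74). With 3 of 3 against at most 1 of 3 lists, 53 arrangements gave at least as many as the 172 then gained and 34 as many as the 218 lost, so those counts were within what other arrangements give. By line, 584 regions were gained and 776 lost in 969, 589 and 1567 in 970, and 296 and 174 in 708. Other splits of the 6 lists gave, over both directions, up to 1830 in 969, 1209 in 970 and 2650 in 708, so the counts of 969 and 708 were within what other splits give, and the 10 splits of 970 are too few for a share under 0.05.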

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

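The tests by other splits of the libraries, by leaving out the 100 highest genes, by level of expression, by vehicle level and by leaving out OHT replicate 2 of 969 were chosen after the results were seen.

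The response of 969 and 970 differed from that of 708 in 6450 genes, and changes of at least 2-fold were mostly increases, 1591 against 174. Low counts stay open: among the 283 of these genes with at least 5 CPM over all libraries 74.2% went up (95% interval 68.8 to 79.0%), but a rise itself carries genes past that minimum, 85 of them with a vehicle mean under 5 CPM, and among the 197 with a vehicle mean of at least 5 CPM in 969 and 970 the share was 63.5% (56.5 to 69.9%), with a lower bound under the 60% set for this test. An expressed gene on the same strand that ended within 10 kb upstream of the start, or reached over it, was found for 29.1% of the 1591 risen genes (interval 26.9 to 31.4%). That is under the 50% set for run-on transcription as the main source but above the 17.5% of matched unchanged genes (15.9 to 19.2%). Genes that end farther than 10 kb upstream were not counted, so this share does not decide whether run-on was the main source. Run-on may contribute to some of them, but the measure does not separate it from counts shared with an overlapping gene. Silent genes far from expressed ones rose by 0.179% of the median rise (SE 0.0127), which argues against background spread evenly per kb as the source of that median rise. These genes were chosen by a low mean over all libraries, OHT included, which leaves out genes with a large rise. Other forms of background were not tested. A biological effect of the genotype was not tested, since 1 control line cannot separate it from other differences between lines.

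None of the other arrangements drawn within lines gave as many as 6450 genes (1 of 100, the real one included, with the highest other at 8). Chance assignment of the OHT and vehicle labels is thus an unlikely source of this count. The arrangements test for no OHT effect in any line, so they do not decide whether the response differed from that of 708. For gene lists 4 of 100 arrangements gave as many as the 11 lists that shifted, the real one included, and the highest other gave 13. A share of drawn arrangements this close to 0.05 may lie past it in another draw, so chance stays open for this count. Of the 11 lists, 2 held with an estimated correlation. Within lines the 10 splits are too few for a share under 0.05. The real counts of genes were 9504 in 969 (highest other 0), 7653 in 970 (highest other 0) and 0 in 708 (highest other 2, 10 of 10 splits as large). Those of lists were 13 in 969 (highest other 11), 14 in 970 (highest other 13) and 1 in 708 (highest other 7, 9 of 10 splits as large).

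Long genes took a smaller share of the counts after OHT, with a log2 ratio of long over short genes that moved by -0.34 relative to 708. Without the 100 highest genes the difference over 969 and 970 was -0.31, so a few genes do not account for it. Level of expression stays open: in only 5 of 10 groups of genes of similar expression did long genes have the lower median log2 fold change, all 5 in the upper range of expression. In the highest group alone, which holds 63.1% of the counts, long genes lay lower by a median difference of -0.40 (95% bootstrap interval -0.464 to -0.321), a test added after the one over all groups had come out in favour of expression level. A biological cause was not tested, and the medians of 970 showed little trend with length.

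The responses of 969 and 970 differed in 320 genes, and 10 of 100 splits within lines gave as many, the real one included (highest other 6077). In all 9 others the libraries of one line stayed together while those of the other line were mixed, so these counts hold the OHT response of the whole line, a structure of the samples, and this test does not decide on chance. Without OHT replicate 2 of 969, which stood apart, 401 genes differed, so that library is not the cause. A weaker response of one size in 970 would give the difference the sign of the mean response in at least 90% of genes, and 78.1% had it (interval 73.3 to 82.3%), while 25.6% had vehicle means at least 4-fold apart (21.2 to 30.7%; 6.70% of other genes), too few for low levels in one line to be the whole cause. A biological difference between the lines stays open and was not tested.

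Single genes in this contrast, each with a test of the difference past the threshold, were Pla2g16 (1.93), Vwce (1.87), Stard9 (1.69), Cyfip1 (-2.84), Thsd4 (-2.38) and Syt14 (-2.17), as log2 fold change in 969 minus that in 970. The percent of fallen genes with a BruUV-seq peak at the start differed from 708 by -1.95 points (exact permutation p = 0.0375), that of other genes by -1.73 (p = 0.181), and fallen minus other genes by -0.22 (p = 0.737), so most of it was shared with other genes. For risen genes minus other genes, the difference from 708 was 2.38 points (exact permutation p = 0.0015, against no OHT effect in any line). With replicate numbers as pairs, the change in 969 and 970 behind it did not pass the threshold.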

How the results depend on the processing

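Counting summits, the replicate block for peaks and peaks on the gene's strand only were tests chosen after the results were seen. Of 767 values under other settings, 687 kept their direction and side of the threshold or stayed within 1.5 times the count, among them 386 of 390 values of 52 named genes and all 50 of the long-gene share. Permutation tests within 1 line cannot pass the threshold, so their values could change in direction only. Most named genes were chosen for large changes without overlap of libraries, which makes a change of side less likely. The exceptions follow, and the cause was not tested unless fewer genes, libraries or peaks explain a lower count. Scaling to the spike-in was not run, and merging peaks within 200 bp moved nothing and so tests nothing. Precision is limited by 3 libraries per group and, for peaks, by an unknown depth.

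With a 2-fold minimum, 2693 genes changed in 969, 1965 in 970, 1765 relative to 708 and 112 between 969 and 970. In 708 DESeq2 called 1 gene, the test without a filter 1, and leaving out each library 0 to 1. Between 969 and 970 DESeq2 called 837 genes and leaving out each library gave 153 to 621. Lists shifted with an estimated correlation were 0 in 969, 1 in 970, 0 in 708 and 2 relative to 708, and with fry 21, 22, 0 and 20. With 1 CPM in 6 libraries they were 8 in 970 and 3 in 708. Leaving out each library gave 2 to 5 lists in 708 and 11 to 18 relative to 708, where the highest came without OHT replicate 3 of 708. Relative to 708, the cholesterol synthesis and cytosolic ribosomal protein lists passed with library totals and with the replicate block. Histone genes passed with the block, and glycolysis and hypoxia genes with library totals and with 1 CPM in 6 libraries. The difference of Cdc73 from 708 turned to -0.0149 without 1 library.

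Libraries of one replicate number deviated together, with a median correlation across groups of 0.152 against -0.0808 for unlike numbers. In 969 the pairs of one number lay above the others, though 1 pair, at 0.0848, was under the limit set for pairing. In all, 14 libraries had all 5 of their best correlations with other groups among libraries of their own number. This pairing was seen in the data only, and the main fit and main permutation tests did not use it. With replicate numbers as a block, 10262 genes changed in 969, 7390 relative to 708 and 774 between 969 and 970, and 2 lists shifted in 708. Under the block the change at starts stayed at -0.80 for fallen genes and 1.88 for risen genes with p = 0.0625 each (exact sign-flip permutation). It moved no other count beyond 1.5 times.

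For peak number (log2), a −log10 q of at least 5 gave -0.13 in 969 and -0.0159 in 708, counting summits gave -0.00598 in 969, and leaving out each library gave -0.0604 to 0.21 in 969 and -0.14 to 0.18 in 708. For the share of peaks at starts (points), the stricter q gave 0.122 in 969 and 0.935 in 708, the same number of peaks gave 0.691 in 708, and leaving out each library gave -6.24 to 0.555 in 969, -3.68 to 3.37 in 708 and -0.516 to 2.88 over 969 and 970. At starts of fallen genes, a 500 bp window gave -0.542 (exact permutation p = 0.345) and leaving out each library -0.937 to -0.625, past the threshold in all but 6 cases with p of 0.05 to 0.06; risen genes gave 1.69 to 2.08.

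Regions gained and lost with the stricter q were 166 gained in 969, 295 and 751 in 970, 82 and 27 in 708, and 18 and 19 in both floxed lines. With the same number of peaks 832 were gained and 627 lost in 970, against 589 and 1567 in the main setting. The excess of losses in 970 thus turned into an excess of gains. With equal peak numbers 162 were gained in 708, and 41 were gained and 15 lost in both floxed lines. With 3 of 3 against at most 1 of 3 lists, 2588 were gained and 1986 lost in 969, 1537 and 4749 in 970, 1880 and 999 in 708, and 172 and 218 in both floxed lines.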

Other observations

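The tests on families of gene symbols and on the places of regions were chosen after the results were seen. Shares of genes changed relative to 708 were also counted by kind of gene, and differences between kinds were not tested. Of 12673 protein-coding genes 2391 (18.9%) rose and 2794 fell by edgeR with Benjamini-Hochberg adjustment, while of 1028 lincRNA genes 26.6% rose and 6.91% fell, of 844 antisense genes 23.7% rose and 5.69% fell, of 784 pseudogenes 13.1% rose and 5.99% fell, and of 2405 other genes 11.1% rose and 10.6% fell. Among families of numbered symbols, 105 of 323 Zfp genes, most of which encode zinc finger proteins, fell and 27 rose. Of the centrosomal Cep genes 18 of 34 fell, of the methyltransferase-like Mettl genes 13 of 23 and of the intraflagellar transport genes (Ift) 9 of 14. The collagen genes (Col) went the other way, with 10 of 16 risen. The median log2 fold change of each of these families kept its sign with RLE size factors and with library totals. None of the 49 Rpl and 42 Rps genes fell, and 1 of 61 histone genes did, although 9 fell in 970 alone. In Fisher's exact tests over 402 pairs of family and direction, 9 passed an adjusted p of 0.05, so chance over families is an unlikely source of all of them, though genes of a family are not independent.

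Other differences between the floxed lines appeared in whole lists, and these were not tested with libraries left out. Histone genes (median 0.32, camera adjusted p = 5.3e-04, but adjusted p = 0.762 with an estimated correlation), cholesterol synthesis genes (0.20, adjusted p = 0.00232, but 0.762) and immediate early genes (0.27, adjusted p = 0.00462, but 0.589) lay higher in 969 than in 970 with 0 genes called over all genes. ATF4 targets (-0.16, adjusted p = 0.00287, but 0.432), homologous recombination genes (-0.11, adjusted p = 0.0162, but 0.589) and checkpoint genes (-0.15, adjusted p = 0.0233, but 0.589) lay lower, with 5, 3 and 0 genes called lower and 0 higher. In 970 alone, cholesterol synthesis genes fell in 19 of 30 cases and rose in 1 (median -0.45, adjusted p = 0.00147, but adjusted p = 0.427 with an estimated correlation).

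Of the 56 regions gained in both floxed lines, 38 lay away from gene starts and outside genes of their own strand, 16 of them over a gene of the other strand, against 9 of the 32 regions lost (two-sided Fisher's exact test, p = 3.98e-04). The test was run on the same regions that prompted it, so it does not decide whether chance placed them. Replicate 3 had the most peaks in 6 of 6 BruUV-seq groups.

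Silent genes far from expressed ones rose slightly in the floxed lines, from 0.000406 to 0.000568 CPM per kb in 969 and from 0.000330 to 0.000467 in 970, and stood at 0.000517 and 0.000513 in 708.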
